A study of Gallus gallus with 4 samples.

How the data were processed

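RNA was measured in 4 samples of the bursa of Fabricius, the lymphoid organ beside the cloaca in which chicken B cells form. Each sample held cells picked from the surface epithelium of healthy, specific-pathogen-free Line-M chicks aged 19 days. The follicle-associated epithelium (FAE) covers the lymphoid follicles, and the interfollicular epithelium (IFE) lies between them. Per the labels' protocols, the tissue was stained with black ink for 5 min so that the FAE could be seen. It was then loosened in 40 mM EDTA with 25 mM Hepes at pH 7.4, for 5 min at room temperature before FAE was collected and for 30 min at 37 °C before IFE was collected. Cells were lifted with a 29G needle under a stereomicroscope. EDTA time and temperature therefore differed between the groups on every array, so the effect of the treatment cannot be told apart from that of the epithelium. Total RNA was amplified and biotin-labelled by a 2-cycle protocol and hybridised to a chicken Affymetrix array.

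Samples were assigned to groups by their titles, which match the cell type label. The source name label of the IFE samples reads FAE, which conflicts with both, and was not used. The labels do not say whether the 2 samples of a group came from separate birds, so p-values measure only the spread between these samples, which may be technical. The sex of the birds is not given.

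The deposited values are linear array intensities, 1 per probe set and array, computed with MAS5 per the submitters' processing notes. The version and settings are not given in the sources used here. Each deposited column has a median of 1 and a minimum of 0.01. Between 99.8% and 99.9% of the values in a column were whole multiples of a common step, within a tolerance of 0.05 steps. Read back through those steps, the columns had medians of 73.4, 79.9, 78.0 and 89.9 in FAE replicates 1 and 2 and IFE replicates 1 and 2, and a 2% trimmed mean of 500.1 on every array. The authors' deposited values thus have the form of signals scaled to a common trimmed mean and then divided by each array's median. No detection calls were used here.

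The table held 38535 probe sets. The 96 array controls were left out, which left 38439. Of these, 27168 named 1 gene, 177 named several and 11094 named none. Symbols came from the platform annotation through the Entrez ID, compared with the gene table of the assembly bGalGal1.mat.broiler.GRCg7b. The ID was missing from that table for 315 probe sets, which kept the annotation's symbol. In total 13051 genes were named. No genome build applies to the array values, so no coordinates are given, and the assembly served only for names and for the chromosome a gene belongs to.

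Each array was scaled to a common 2% trimmed mean and log2 was taken without an offset. Probe sets were tested if their mean scaled signal over the 4 arrays reached the 40th percentile of all probe sets that are not controls (a scaled signal of 0.695), which left out 15376 dim ones and kept 23063. FAE and IFE were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), two-sided, with the Benjamini-Hochberg adjustment and a threshold of 0.05. Adjusted p-values below are from that fit unless another test is named. Values given as a level are scaled signals, as mean ± SD with n = 2, and log2 fold changes are FAE over IFE with their standard error (SE). A gene was represented by the tested probe set with the highest mean log2 signal among those naming 1 gene, which gave 10419 genes. A probe set was taken as not above background in a group where it lay, on both arrays, under the 95th percentile of 744 unnamed probe sets of the array that lack the chicken prefix. That level was 0.671 and 0.683 on the FAE arrays and 0.722 and 1.02 on the IFE arrays. For such genes the fold is a lower bound against that level, written as at least N-fold. Where the signal was under that level on only 1 array of a group, the fold was left as computed and may be overstated.

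Gene lists of cell type markers and pathways were tested with camera (limma) at its preset correlation of 0.01 if at least 5 members were measured, with p adjusted over 20 lists. Camera with an estimated correlation and fry were run beside it. Of 461 list entries, 367 matched a gene on the array, some under a newer symbol such as HES4 for HES1, GADD45G for GADD45B and CATH1 for a cathelicidin. Most genes named in the Results follow a rule: the 12 largest log2 fold changes in each direction among called genes with non-overlapping groups and a symbol that is no placeholder, up to 4 members of each list by adjusted p, and every measured M cell gene. Further list members were named outside this rule: MKI67, PCNA, CDK1, IRF8, MARCO, PAX5, EPCAM, CDH1, HMGCS1, ACACA, CD74, BLB1 and the heat shock genes. The family, leukocyte and W-linked genes of the closing section were also named outside it. Of the 12 largest decreases, 1 gene is counted but not named in the text. ANXA10 and PRNP were listed because the study is known to have singled them out from these samples, so they are not independent evidence. The groups, tests, lists, rule and alternatives were fixed before the data were examined, apart from those stated to be chosen later.

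The alternatives were quantile normalization, scaling to a common median, the deposited values without rescaling, an offset at the 20th percentile, no filter, a filter at the 60th percentile, no intensity trend, leaving out probe sets that may cross-hybridise, the replicate number as a block, each sample left out, and the mean of all probe sets of a gene. Leaving out genes on the sex chromosomes and leaving out probe sets without the chicken prefix were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.

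The fit was tested on simulated data with 23063 probe sets, 200 of them changed, in 20 runs. With spreads drawn from the fitted prior, 4.76% of the calls were unchanged probe sets, and 13.6% of changes of 2 and 47.5% of changes of 3 on the log2 scale were called. With the spreads estimated for each probe set, 10.1% of the calls were unchanged probe sets and 60.8% and 86.6% of those changes were called. Every changed probe set that was called had the right sign. In 100 further simulations, 1 list of 15 genes was shifted by 1 on the log2 scale. Camera with the preset correlation called the shifted list every time and called 0.368% of the unshifted lists. Genes were simulated independently of each other, so this rate does not cover lists whose members are correlated. In the data, estimated correlations ran from -0.10 for mucous secretory genes to 0.52 for stratified epithelium, with 0.27 for macrophage and dendritic cell genes. With an estimated correlation camera called the shifted list 0 times, so that version had no power for such a list with 2 arrays per group. Other list sizes and shifts were not simulated. The 2 arrays per group limit the precision.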

Results

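Gene expression was measured in 2 samples of FAE and 2 samples of IFE from the bursa of 19-day-old chicks, on 4 single-colour arrays. Across the 23063 tested probe sets, log2 signals correlated at r = 0.965 between the FAE arrays and at 0.917 between the IFE arrays. The 4 correlations between an FAE and an IFE array lay between 0.850 and 0.894, below both. The median absolute log2 difference was 0.252 between the FAE replicates and 0.482 between the IFE replicates, so no arrays were near identical. IFE replicate 2 differed from the others in signs of RNA quality. Its 3'/5' signal ratio of beta-actin was 31.2, against 14.4 to 18.6 on the other arrays, and its background level was 1.02, against 0.671 to 0.722. Poly-A spike-in controls had mean signals of 35.6 and 38.97 on the FAE arrays and of 17.1 and 26.2 on the IFE arrays.

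The series addresses how the epithelium over the follicles differs from the epithelium between them. Among the genes with the largest increases in FAE were the cartilage matrix protein gene LECT1 (chondromodulin), SPP2, APOH, the complement subunit C1QA and the cytokine IL1B. IFE in turn had higher signal of the immediate early gene IER3, the Notch ligand JAG2, the growth factor gene AREG, the metabolic kinase PDK4 and the endodermal and endothelial transcription factor SOX7. For all of these genes, the effect of the EDTA time and temperature cannot be told apart from that of the epithelium. In total, 656 genes were higher and 411 lower in FAE (limma, adjusted p under 0.05) out of 10419 tested, and 647 and 399 of these differed at least 2-fold. At the level of probe sets, 1204 were higher and 695 lower, so 63.4% of the calls were higher in FAE, and 5517 passed an unadjusted p of 0.05. By size alone, 1355 probe sets were at least 2-fold higher on both FAE arrays than on either IFE array and 837 were at least 2-fold lower. The groups did not overlap for 55.9% of the probe sets, where chance gives 33.3%. The counts moved with each sample left out. Genes higher and lower in FAE numbered 123 and 25 without FAE replicate 1, 221 and 109 without FAE replicate 2, 1825 and 1433 without IFE replicate 1, 1215 and 1084 without IFE replicate 2, and 244 and 49 without the intensity trend.

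**Figure D1:**
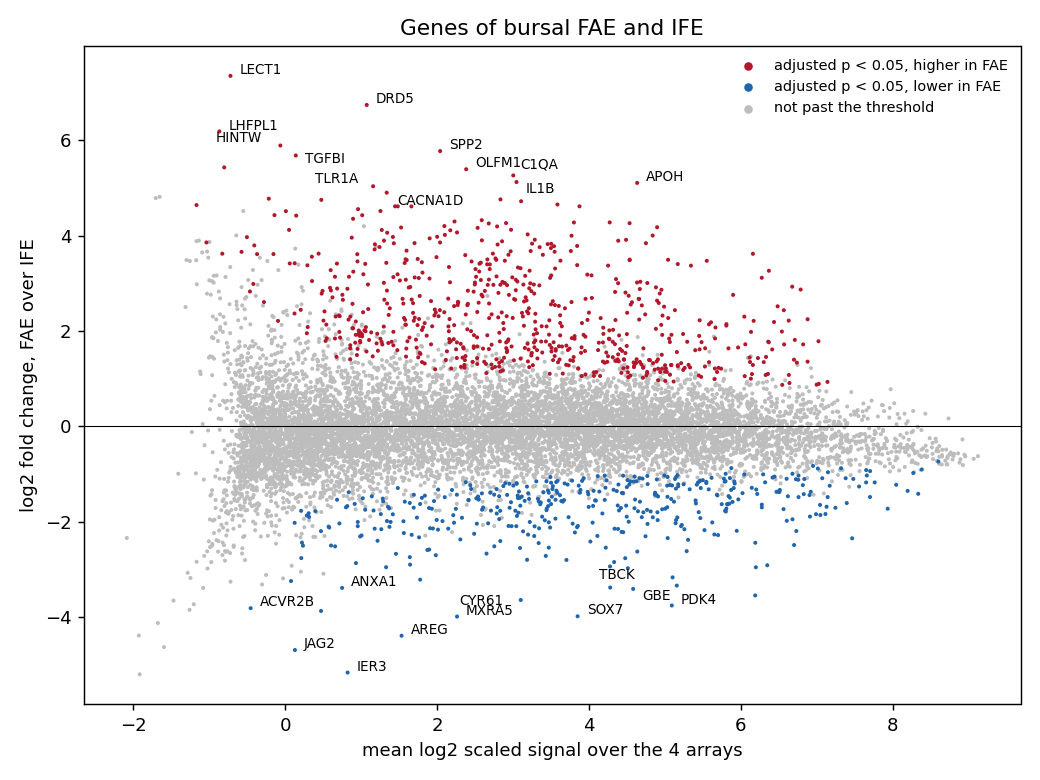
Each point is a gene, with its mean log2 scaled signal over the 4 arrays on the horizontal axis and its log2 fold change (FAE over IFE) on the vertical axis. Red and blue points are the 656 genes higher and the 411 lower in FAE, grey points did not pass the threshold, and the largest called changes with non-overlapping groups are labelled, 12 higher and 11 lower in FAE.

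Among the 12 genes with the largest increase in FAE, 6 were not above background on either IFE array. Their increases were at least 25.4-fold for the dopamine receptor DRD5, 16.1-fold for the calcium channel CACNA1D, 9.21-fold for the matrix protein TGFBI, 9.05-fold for LECT1, 8.60-fold for the W-linked gene HINTW and 5.46-fold for LHFPL1, with adjusted p between 0.00208 and 0.0116. HINTW had signals of 10.2 and 5.31 in FAE and 0.0864 and 0.178 in IFE. APOH, a plasma glycoprotein gene, rose from 4.24 ± 0.288 (SD, n = 2) in IFE to 147 ± 16.8 in FAE, a log2 fold change of 5.11 (SE 0.24, adjusted p = 0.00208). C1QA had a log2 fold change of 5.27 (SE 0.60), SPP2 of 5.78 (SE 0.48), OLFM1 of 5.40 (SE 0.65) and the Toll-like receptor TLR1A of 5.04 (SE 0.78). IL1B changed by 5.13 (SE 1.02, adjusted p = 0.0291), with unequal signals of 4.90 and 0.398 on the IFE arrays. C1QA (0.651) and OLFM1 (0.373) lay under background on IFE replicate 1. SPP2 (0.339), TLR1A (0.155) and IL1B did so on IFE replicate 2, so the sizes of these changes rest partly on signals at background. Of these 12 calls, 5 remained without FAE replicate 1, 9 without FAE replicate 2, and all 12 without either IFE replicate. The adjusted p of HINTW was 0.254 and that of IL1B 0.113 without FAE replicate 1. The other probe set of DRD5 gave 0.08 and did not pass, so its probe sets disagree. Without FAE replicate 1 that probe set had the higher mean log2 signal and stood for DRD5, at 0.07, while the one named here gave 6.49. The loss of the DRD5 call there therefore reflects the change of probe set.

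Among the 12 genes with the largest decrease in FAE, IER3 was at least 15.6-fold, JAG2 at least 8.20-fold and the activin receptor ACVR2B at least 4.03-fold lower, since the tested probe set of each was not above background on either FAE array. Another JAG2 probe set, too dim to be tested, went the other way, with deposited values of 0.809 and 0.844 in FAE and 0.136 and 0.558 in IFE. AREG, an epidermal growth factor receptor ligand, had signals of 0.491 and 0.813 in FAE and 7.36 and 23.8 in IFE, a log2 fold change of -4.39 (SE 0.57, adjusted p = 0.00690). PDK4, which restrains pyruvate oxidation, had a log2 fold change of -3.76 (SE 0.32), SOX7 of -3.98 (SE 0.30), the matrix gene MXRA5 of -3.99 (SE 0.66) and the secreted matrix-associated gene CYR61 of -3.64 (SE 0.38). GBE changed by -3.41 (SE 0.40) and ANXA1 by -3.39 (SE 0.76, adjusted p = 0.0426). On FAE replicate 1, the signals of AREG (0.491), MXRA5 (0.605) and ANXA1 (0.220) lay under background. TBCK changed by -3.38 (SE 0.45) on its brightest probe set, whereas 2 other probe sets gave 0.75 and 0.43 and did not pass, so its probe sets disagree. Of these 12 calls, 9 remained without FAE replicate 1, 12 without FAE replicate 2, 10 without IFE replicate 1 and 11 without IFE replicate 2. For JAG2 the value without IFE replicate 1 was 0.33, because another of its probe sets then entered the test and had the higher mean log2 signal. It took the place of the one named here, which gave -4.61, so the loss of the JAG2 call there reflects the change of probe set.

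FAE contains cells likened to intestinal M cells, and 12 of 16 M cell genes of mammals were measured. GP2, SPIB, RELB and ICAM2 matched no gene on the array, so the list was tested without them. SOX8, a transcription factor of M cell maturation, rose from 5.53 ± 1.59 (SD, n = 2) in IFE to 81.6 ± 17.5 in FAE, a log2 fold change of 3.90 (SE 0.30, adjusted p = 0.00230). Clusterin (CLU) changed by 4.43 (SE 0.64), TNFAIP2 by 1.90 (SE 0.32), MARCKSL1 by 1.62 (SE 0.20) and TNFRSF11A, the receptor of RANKL, by 0.88 (SE 0.19, adjusted p = 0.0401), which did not pass without the filter (0.104). The CLU signal on IFE replicate 2, at 0.219, lay under background. ANXA5 was lower in FAE, with a log2 fold change of -1.08 (SE 0.25, adjusted p = 0.0470), and lost its call with quantile normalization (adjusted p = 0.0586), with the common median (0.0921) and without the filter (0.0712). The remaining 6 did not pass: SCG5 (adjusted p = 0.153), NFKB2 at 0.44, CTSE at 0.04, CCL20 at -0.03, ESRRG at -0.29 and TRAF6 at -0.31. As a list, M cell genes were higher in FAE than other genes (camera, median log2 fold change 0.66, adjusted p = 0.0196), and the adjusted p = 0.348 with an estimated correlation. Adjusted over the list alone, 6 members were higher and 1 was lower. The list call was lost without IFE replicate 1 (adjusted p = 0.0985) and without probe sets that may cross-hybridise (median 0.11, adjusted p = 0.114). SOX8 alone of the 6 called members passed without FAE replicate 1 (adjusted p = 0.0281), and SOX8 and CLU passed without FAE replicate 2. Macrophage and B cell markers rose more on the same arrays, with medians of 3.23 and 2.95.

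Of the genes the study singled out, the prion protein gene PRNP was higher in FAE, at 63.2 ± 5.07 (SD, n = 2) against 18.4 ± 7.65, a log2 fold change of 1.84 (SE 0.32, adjusted p = 0.0193). Its adjusted p was 0.220 without FAE replicate 1, 0.122 without FAE replicate 2 and 0.0932 without the intensity trend. ANXA10 was left out as dim, with scaled signals of 0.0275 and 0.235 on the FAE arrays and 0.193 and 0.260 on the IFE arrays, and no fold was computed. These genes were picked from these samples and give no independent evidence.

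**Figure D2:**
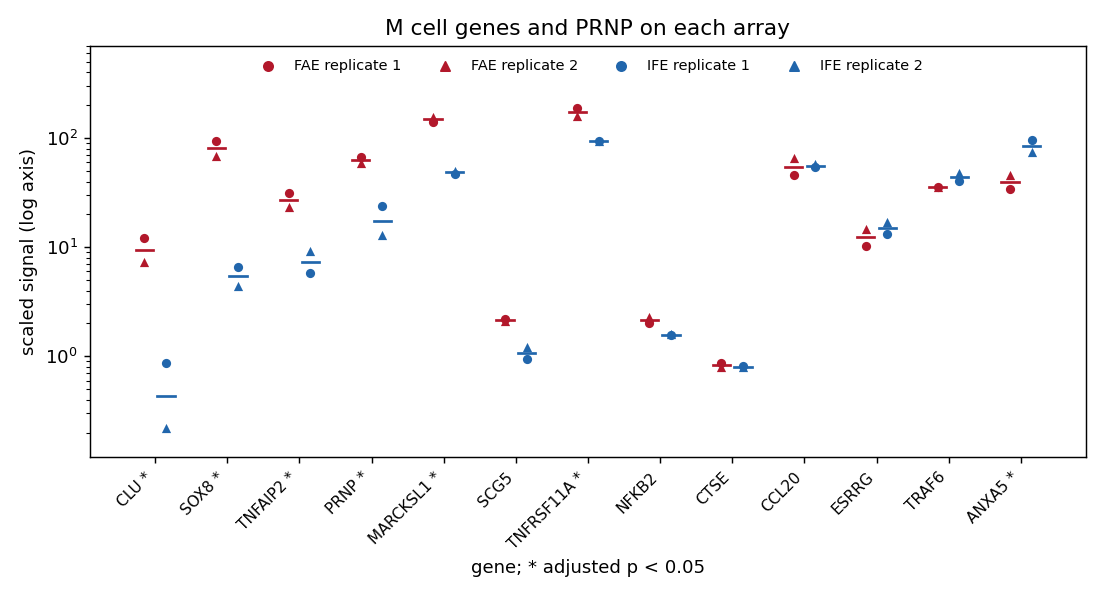
Scaled signals (log axis) of the 12 measured M cell genes and PRNP on each array, ordered by fold change, with a horizontal bar at each group's geometric mean and an asterisk where the adjusted p was under 0.05. SOX8 had signals of 94.0 and 69.3 on the FAE arrays and of 6.65 and 4.41 on the IFE arrays, while CCL20 overlapped between the groups.

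Markers of macrophages and dendritic cells and of B cells were the lists with the highest medians. For macrophages and dendritic cells, 9 of 13 measured members were higher in FAE and none was lower (median log2 fold change 3.23, camera adjusted p = 1.98e-08, and adjusted p = 0.348 with an estimated correlation). The macrophage and B cell transcription factor SPI1 rose from 26.7 ± 0.538 (SD, n = 2) to 257 ± 2.72, and the macrophage receptor CSF1R rose from 9.89 ± 1.72 to 112 ± 19.1. The phagocytic receptor MERTK had a log2 fold change of 4.01 (SE 0.38) and the leukocyte integrin ITGB2 of 3.92 (SE 0.33). IRF8 at -1.27 (adjusted p = 0.0719) and MARCO at -0.69 did not pass. For B cells, 8 of 12 members were higher and none lower (median 2.95, adjusted p = 1.96e-07, and adjusted p = 0.348 with an estimated correlation). The kinases BTK and SYK had log2 fold changes of 4.27 (SE 0.28) and 3.74 (SE 0.32), the B cell receptor component CD79B of 3.30 (SE 0.30) and IKZF3 of 2.71 (SE 0.27), while another probe set of IKZF3 gave -0.13 and did not pass. PAX5 had -0.85 (adjusted p = 0.315). Adjusted over the list alone, 11 macrophage and dendritic cell members were higher and 1 lower, and 10 B cell members were higher. The 8 members named here as higher kept their calls without each sample in turn.

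T cell markers did not pass as a list (median 0.32, adjusted p = 0.101), and CD3E, a subunit of the T cell receptor complex, was the only member of 10 called, with a log2 fold change of 1.41 (SE 0.25, adjusted p = 0.0212). By adjustment over the list alone, 1 member was called as well. The CD3E call was lost without FAE replicate 1 and without FAE replicate 2. The list passed without FAE replicate 2, with a median of 0.51, but its median turned to -0.0750 without FAE replicate 1.

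Genes of the cell cycle were higher in FAE as a list, with 13 of 27 measured members higher and none lower (median log2 fold change 1.79, camera adjusted p = 1.43e-10, and adjusted p = 0.348 with an estimated correlation). The spindle checkpoint kinase BUB1B rose from 0.845 ± 0.0868 (SD, n = 2) in IFE to 10.9 ± 0.554 in FAE, and the condensin gene SMC2 from 1.17 ± 0.207 to 13.7 ± 1.49. The BUB1B signal on IFE replicate 2, at 0.784, lay under background. CDC20 and KIF11, which act in mitosis, had log2 fold changes of 2.60 (SE 0.29) and 2.85 (SE 0.31). MKI67, a general marker of cycling cells, was also called, at 3.02, while PCNA at 0.08 and CDK1 at -0.46 did not pass. With p adjusted over the list alone, 19 members were higher. BUB1B and SMC2 kept their calls without each sample, and CDC20 and KIF11 lost them without FAE replicate 1 (adjusted p = 0.0501 and 0.0538). Macrophage and B cell markers were higher on the same arrays, with medians of 3.23 and 2.95.

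Genes of cholesterol and fatty acid synthesis were also higher as a list, with 9 of 16 members higher in FAE and none lower (median 1.89, adjusted p = 5.90e-07, and adjusted p = 0.348 with an estimated correlation). FDFT1, the squalene synthase, rose from 7.38 ± 0.302 (SD, n = 2) to 59.6 ± 9.37, and SQLE, which acts on squalene, rose from 11.6 ± 0.341 to 81.1 ± 15.7. FDPS changed by 4.62 (SE 0.64) and the fatty acid synthase FASN by 1.85 (SE 0.25). The FDPS signal on IFE replicate 2, at 0.268, lay under background. HMGCS1 had 0.22 and ACACA -0.31, and neither passed. Adjusted over the list alone, 10 members were higher. FASN lost its call without either FAE replicate, and the other 3 kept theirs without each sample. Another probe set then stood for FASN, at 1.21 (adjusted p = 0.422) without FAE replicate 1 and 1.51 (0.191) without FAE replicate 2. The one named here gave 1.72 and 1.98, and adjusted over all probe sets it did not pass either (0.192 and 0.0912). On the same arrays, macrophage and B cell markers were higher, with medians of 3.23 and 2.95.

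Genes of endosomes and lysosomes were higher as a list (median 0.64, adjusted p = 4.89e-04, and adjusted p = 0.495 with an estimated correlation), with 7 of 35 members higher and 1 lower. The caveolin CAV2 had a log2 fold change of 2.68 (SE 0.26), the lysosomal lipase LIPA of 2.61 (SE 0.36) and the cathepsin CTSZ of 2.31 (SE 0.28). The proton pump subunit ATP6V0D2 went the other way, at -2.22 (SE 0.25, adjusted p = 0.00452). Adjusted over the list alone, 15 members were higher and 3 lower. The list did not pass by fry (adjusted p = 0.0971). Macrophage markers, whose cells are rich in lysosomes, rose more on the same arrays (median 3.23). The calls of these 4 genes were lost without FAE replicate 1 (adjusted p = 0.0571 for CAV2) and kept without each of the other samples.

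Early response and heat shock genes formed the list with the lowest median. Of 19 measured members, 11 were lower in FAE and none higher (median log2 fold change -1.26, camera adjusted p = 1.35e-08, and adjusted p = 0.348 with an estimated correlation). DUSP1, a phosphatase induced by stress and growth signals, stood at 399 ± 5.97 (SD, n = 2) in IFE and 78.8 ± 10.5 in FAE. JUN had a log2 fold change of -1.73 (SE 0.18), EGR1 of -1.41 (SE 0.18) and GADD45G of -2.27 (SE 0.27). The heat shock genes were split: HSPA2 at -2.95 and HSPB9 at -2.91 passed, while HSPA8 at -0.34, HSP90AA1 at -0.32, DNAJA1 at -0.35 and HSPH1 at 0.69 did not. When adjusted over the list alone, 13 members were lower. EGR1 lost its call without FAE replicate 1 (adjusted p = 0.0505) and without FAE replicate 2 (0.0544), as did GADD45G (0.0968 and 0.0540), and DUSP1 and JUN kept theirs without each sample. IFE was in EDTA for 30 min at 37 °C and FAE for 5 min at room temperature, so the time and temperature moved with this list.

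Epithelial junction and keratin genes were slightly lower in FAE as a list (median -0.48, adjusted p = 0.0341, and adjusted p = 0.558 with an estimated correlation). The epithelial transcription factor ELF3 had a log2 fold change of -1.48 (SE 0.21), the desmosomal gene PKP2 of -1.42 (SE 0.21) and the intestinal cadherin CDH17 of -1.40 (SE 0.31), and these were the 3 called members of 18. The general epithelial markers EPCAM at -0.55 and CDH1 at -0.64 did not pass. When adjusted over the list alone, 3 members were lower. The list call was lost with quantile normalization (median -0.11, adjusted p = 0.312), without probe sets that may cross-hybridise (median -0.24, 0.149) and without FAE replicate 1 (median -0.30, 0.0813). It was also lost without the intensity trend (0.0711), without IFE replicate 1 (0.141) and by fry (0.151). None of the 3 genes passed without FAE replicate 1, and ELF3 alone passed without FAE replicate 2 (adjusted p = 0.0323). CDH17 also lost its call with quantile normalization (0.0602), the common median (0.0556) and the mean of all probe sets (0.0615), and without the filter (0.0596). Macrophage and B cell markers, with medians of 3.23 and 2.95, were higher on the same arrays.

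Genes of stem cells and of Notch and Wnt signalling were lower as a list (median -0.89, adjusted p = 0.0341, and adjusted p = 0.495 with an estimated correlation), with 5 of 19 members lower and 2 higher. Besides JAG2, the Notch target HES4 had a log2 fold change of -2.62 (SE 0.26) and the Notch ligand DLL1 of -1.37 (SE 0.20). The adhesion receptor CD44 was higher, at 1.34 (SE 0.24). When adjusted over the list alone, 6 members were lower and 2 higher. The list call was lost without IFE replicate 1 (median -0.44, adjusted p = 0.151) and without IFE replicate 2 (median -0.52, 0.0787). It was kept with a median of -0.37 without FAE replicate 1 and of -0.38 without the filter. The calls of CD44 and DLL1 were lost without FAE replicate 1 (0.388 and 0.197) and without FAE replicate 2 (0.210 and 0.0974). The same arrays had higher macrophage and B cell markers, with medians of 3.23 and 2.95.

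**Figure D3:**
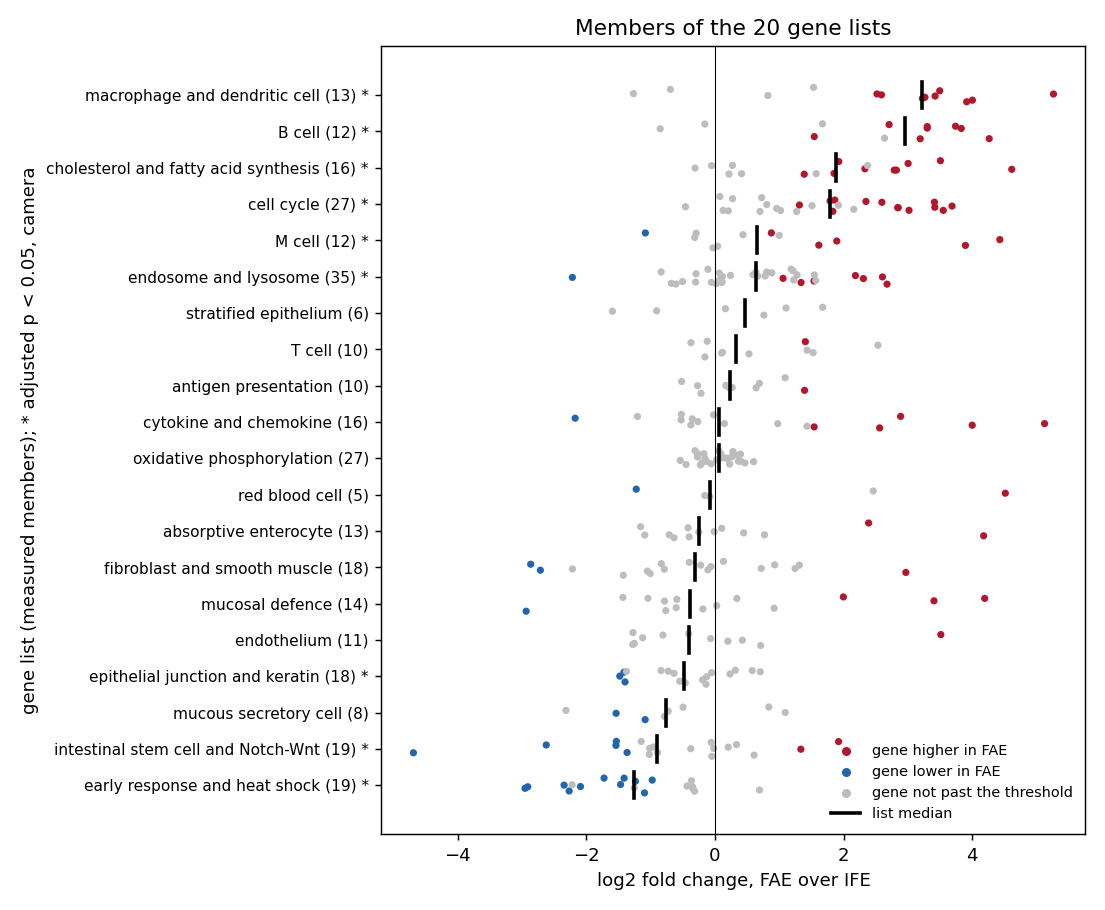
Each point is a measured member of one of the 20 gene lists, placed by its log2 fold change (FAE over IFE), red or blue where the gene was higher or lower in FAE at an adjusted p under 0.05 and grey otherwise, with a black bar at the list median. The medians ran from -1.26 for early response and heat shock genes to 3.23 for macrophage and dendritic cell markers, and an asterisk marks the 9 lists past the threshold in camera, 6 higher and 3 lower.

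Other cell type lists did not pass in camera, although single members did in all but the stratified epithelium list. By fry the mucous secretory (adjusted p = 0.0452) and red blood cell (0.0293) lists passed. In the mucous secretory list (median -0.76, adjusted p = 0.0923), AGR2, which folds mucins, had a log2 fold change of -1.09 (SE 0.25) and ST6GALNAC1 of -1.54 (SE 0.26), 2 of 8 members, and 3 were lower when adjusted over the list alone. That list passed without FAE replicate 1 (0.0366) and had a median of -0.45 (0.150) without FAE replicate 2 and an adjusted p of 0.378 without IFE replicate 2. In the absorptive enterocyte list (median -0.25, mean 0.25, adjusted p = 0.990), the apolipoprotein APOA1 at 4.18 (SE 0.56) and villin (VIL1) at 2.39 (SE 0.33) were higher, and adjusted over the list alone 2 of 13 members were higher and 1 lower. No member of the stratified epithelium list passed (median 0.46, adjusted p = 0.519), where KRT5 had 1.68 (adjusted p = 0.0524) and EVPL -1.59 (adjusted p = 0.0867). Of its 6 members, 2 were higher and 1 lower when adjusted over the list alone. Fibroblast and smooth muscle markers (median -0.31, adjusted p = 0.343) went both ways, with the collagens COL6A2 at -2.72 (SE 0.38) and COL5A1 at -2.87 (SE 0.53) lower and vimentin (VIM) at 2.97 (SE 0.55) higher, and adjusted over the list alone 3 were lower and 1 higher of 18. That list passed as lower without FAE replicate 2 (median -0.73), but its median was 0.01 without FAE replicate 1. The COL5A1 signal on FAE replicate 1, at 0.408, lay under background. CDH5 was the only endothelial marker of 11 that passed, at 3.51 (SE 0.32), and the endothelial list did not (median -0.41, adjusted p = 0.842), with 1 member higher and 1 lower when adjusted over the list alone. Of the 5 red blood cell genes (median -0.08, mean 1.103, adjusted p = 0.519), the globin HBA1 was at least 5.61-fold higher and EPB41 had -1.22 (SE 0.26), and adjusted over the list alone 2 were higher and 1 lower. Of these genes, AGR2, ST6GALNAC1, HBA1, EPB41, COL6A2 and VIM lost their calls without either FAE replicate, and VIL1 and COL5A1 without FAE replicate 1. HBA1 had a value of 1.87 without FAE replicate 2, from another probe set, while the one named here gave 4.20.

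The immune and respiratory lists outside the cell type markers did not pass in camera either. Cytokine and chemokine genes (median 0.06, adjusted p = 0.1204) included 5 higher and 1 lower of 16, and the list passed without FAE replicate 2 (0.0287) and without probe sets that may cross-hybridise (0.0382). Its median was 0.79 (0.0985) without IFE replicate 1. The B cell survival factor gene TNFSF13B, known as BAFF, rose from 3.51 ± 1.17 (SD, n = 2) in IFE to 54.7 ± 1.64 in FAE, and IL18 changed by 2.56 (SE 0.31). The 2 interleukin-8 genes moved apart, IL8L1 at least 5.60-fold higher and IL8L2 at -2.18 (SE 0.29), and adjusted over the list alone 6 were higher and 2 lower. For mucosal defence (median -0.39, mean 0.18, adjusted p = 0.807), avidin (AVD) at 3.41 (SE 0.49), DMBT1 at 2.00 (SE 0.33) and TLR2A at 4.20 (SE 0.79) were higher and the cathelicidin CATH1 at -2.94 (SE 0.30) was lower, 4 of 14 members, and adjusted over the list alone 3 were higher and 3 lower. On IFE replicate 2, TLR2A (0.629) and DMBT1 (0.888) lay under background. In antigen presentation (median 0.24, adjusted p = 0.144), DMA was the only called member of 10, at 1.39 (SE 0.31), and adjusted over the list alone 2 were higher. The class II-associated invariant chain CD74 and the class II chain BLB1 had high signal in both groups, at 457 ± 94.98 and 384 ± 83.5 in FAE and 405 ± 62.3 and 315 ± 19.9 in IFE. With quantile normalization the antigen presentation list passed (adjusted p = 0.00394), as it did by fry (0.0293), while DMA lost its call (0.0621). None of the 27 oxidative phosphorylation genes passed, by either adjustment (median 0.06, adjusted p = 0.842). COX4I1 had -0.54 (SE 0.18) and NDUFA5 -0.45 (SE 0.23). Without FAE replicate 1 the calls of IL18, IL8L1, IL8L2, TLR2A, AVD, DMBT1 and DMA were lost (adjusted p = 0.0865 for IL18), and without FAE replicate 2 those of IL8L1, TLR2A, DMBT1 and DMA (0.145 for DMA).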

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

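Leaving out genes on the sex chromosomes, and leaving out probe sets without the chicken prefix, were chosen after seeing the data, and all other settings here were planned. Genes higher and lower in FAE numbered 632 and 384 without the sex-linked genes, and probe sets 1204 and 694 without those lacking the prefix.

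Counts stayed within 1.5 times of the main ones with quantile normalization, both other scalings, the offset, the stricter filter, the mean of all probe sets, and without probe sets that may cross-hybridise. Scaling to a common median left the deposited values unchanged, since every column already had a median of 1. It and the deposited values without rescaling are therefore the same check. Without the intensity trend, probe sets higher and lower in FAE numbered 449 and 102 and genes 244 and 49. Without the filter, probe sets 2-fold apart numbered 2035 higher and 1774 lower, because dim ones were compared too. Without each sample in turn, probe sets higher ran from 191 to 3567 and lower from 44 to 2471, genes higher from 123 to 1825 and lower from 25 to 1433, probe sets 2-fold higher from 1517 to 2862 and 2-fold lower from 1408 to 2077, and lists lower from 1 to 4. With 1 FAE sample, the spread comes from the IFE pair, whose median absolute log2 difference of 0.482 exceeded the 0.252 of the FAE pair. With 1 IFE sample, the spread comes from the closer FAE pair, and more genes were called. A call kept without an IFE replicate therefore says little about its stability. With an estimated correlation, 0 lists were higher and 0 lower. Fry passed 10 lists, but neither endosome and lysosome nor epithelial junction genes, and added mucous secretory, antigen presentation and red blood cell genes. A fit with the replicate number as a block raised the count of lower probe sets to 1083 and of lower genes to 651. No label says what samples with the same replicate number have in common. The differences of replicate 1 minus replicate 2 in FAE and in IFE correlated at 0.0246 across probe sets. Scaling to a common median moved the median log2 fold change of tested probe sets from -0.07 to 0.06.

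Of 81 called genes that the naming rule picked, 35 kept their call without FAE replicate 1, 55 without FAE replicate 2, 79 without IFE replicate 1 and 80 without IFE replicate 2. Without the intensity trend, 44 kept it: all the named B cell, macrophage and cell cycle genes did, while of the M cell genes only SOX8 did, and PRNP, CD3E, JUN, AREG and the epithelial junction genes did not. Quantile normalization ended the calls of ANXA5, CDH17, AGR2 and DMA, the common median those of ANXA5, CDH17 and ANXA1, the mean of all probe sets those of CDH17, TBCK, HBA1 and DLL1, and leaving out the filter those of ANXA1, ANXA5, TNFRSF11A, CDH17, AGR2, EPB41 and DMA. CCL20, not called, turned to 0.0140 with quantile normalization, 0.0991 with the common median and without rescaling, and ran from -0.291 to 0.231 without each sample. CTSE, not called, ran from -0.0271 to 0.108 without each sample and reached 0.188 with quantile normalization. Without each sample, JAG2, called, ran from -4.84 to 0.334, with the reversed value from another probe set. DRD5, called, ran from 0.0668 to 7.39 for the same reason. The reversed list medians were all of lists not called. Red blood cells had 0.0242 with quantile normalization, 0.0476 with the common median and without rescaling, and 0.184 without the filter. Cytokines had -0.0214 without the filter and -0.0900 with the mean of all probe sets. Without each sample in turn, medians ran from -0.0750 to 0.694 for T cells, -0.733 to 0.01005 for fibroblasts, -0.0192 to 0.103 for oxidative phosphorylation, -0.488 to 0.0182 for enterocytes, -0.00457 to 0.818 for stratified epithelium, -0.796 to 0.273 for endothelium and -0.597 to 0.155 for mucosal defence. The cause of these reversals was not tested, apart from JAG2.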

Other observations

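The gene families in the next 2 paragraphs, the test of the share of epithelium and both tests on the early response genes were chosen after the results were seen.

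The RPL family of ribosomal protein genes and the Krüppel-like factors (KLF) passed as lower in FAE. Genes were grouped by the letters before the first digit of their symbol, and 171 families with at least 8 measured members were tested with camera, of which 6 passed. In the large ribosomal subunit family RPL, 39 of 40 members had a negative log2 fold change, with a median of -0.64 (adjusted p = 7.01e-08, and adjusted p = 0.988 with an estimated correlation), although only RPL21, RPL37 and RPL8 passed singly. Its median was -0.22 with quantile normalization and -0.51 with the common median. The RPS family also passed (median -0.52, adjusted p = 0.00414, and adjusted p = 0.988 with an estimated correlation), but it mixes small subunit genes with kinases such as RPS6KA1, none of its members was called, and its median was -0.28 with quantile normalization. Of the Krüppel-like factors, transcription factors that often respond to stress and differentiation, 4 of 9 members were lower (median -1.15, adjusted p = 0.00375, and adjusted p = 0.988 with an estimated correlation), namely KLF15 at -2.07, KLF2 at -2.09, KLF3 at -1.58 and KLF10 at -1.42. The median of this family was -0.72 without IFE replicate 2. KLF2 belongs as well to the early response list, and EDTA time and temperature differed between the groups.

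Of the DOCK family, 5 of 8 members were higher in FAE (median 2.18, adjusted p = 8.61e-05, and adjusted p = 0.988 with an estimated correlation), among them DOCK2 at 3.84 and DOCK8 at 3.78, which blood cells use for migration, and DOCK4 at 3.79. Genes with symbols that begin with CD were higher for 15 and lower for 1 of 41 members (median 1.15, adjusted p = 3.43e-05, and adjusted p = 0.988 with an estimated correlation), with CD38 at 4.30, CD200R1A at 4.26 and CD72 at 3.62 among the higher and CD99 at -1.39 the lower, and the median was 0.60 without IFE replicate 1. Genes with symbols that begin with IL, mostly interleukins and their receptors, were higher for 10 and lower for 1 of 33 (median 0.47, adjusted p = 0.0335, and adjusted p = 0.988 with an estimated correlation), and the median was 0.74 without IFE replicate 2. The directions of the 6 families held under each scaling. On these arrays the macrophage and B cell markers were also higher, with medians of 3.23 and 2.95. DOCK2 and DOCK8 belong as well to the leukocyte list of the next paragraph. Of the called CD genes, CD79B, CD3E, CD83, CD63 and CD44 belong to the B cell, T cell, macrophage, endosome and stem cell lists, respectively. The called IL1B, IL18, IL8L1 and IL8L2 belong to the cytokine and chemokine list, which did not pass in camera.

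The leukocyte markers raised the question whether leukocytes were collected with the FAE. A separate list of genes shared by most leukocytes had 16 measured members, of which 13 were higher in FAE and 0 lower, with a median log2 fold change of 2.98, consistent with that explanation. Among them were LCP1, at 228 and 230 in FAE against 35.4 and 19.6 in IFE, and DOCK2, at 110 and 95.02 against 9.03 and 5.59. A lower share of epithelium alone was taken to raise the markers of all other cell types alike. B cell and macrophage members lay 3.59 above fibroblast, smooth muscle and endothelium members (difference of medians). Without each sample in turn the list medians ran from 2.34 to 3.49 and from 2.82 to 3.28 against -0.733 to 0.01005 and -0.796 to 0.273. These values argue only against an equal rise of all other cell types. The list medians were known when this test was chosen, and it cannot decide on epithelium replaced mainly by leukocytes. Expression of these genes by the FAE cells themselves was not tested and stays open.

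The higher early response genes of IFE may reflect its collection, its biology or RNA quality. The RNA quality of IFE replicate 2 is argued against, since the list median was -1.24 without that sample. The longer and warmer EDTA step cannot be told apart from the epithelium, because every IFE sample had it and no FAE sample did, and the list median of -1.26 carries both. A difference between the epithelia themselves stays open and untested.

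HINTW lies on the W chromosome, which only female birds carry, and its signal was above background on both FAE arrays and on neither IFE array, so birds of different sex would make Z-linked genes lower in FAE. The median log2 fold change of 475 Z-linked genes minus that of 9805 autosomal genes was -0.11 (permutation p = 0.00152, with genes as the units), short of the 0.2 decrease set beforehand for a sex difference and outside the 0.1 set for none. That difference ran from -0.20 to -0.08 over the 4 pairs of an FAE and an IFE array and was -0.03 and -0.05 within the groups, while chromosomes 7 and 2 had medians of -0.17 each, near the -0.18 of Z. The other 6 W-linked genes had a median of -0.0369, inside the range written beforehand for an effect at HINTW alone, but they went from 1.61 for HNRNPKL to -1.71 for NEDD4L, so that result was set to undecided after it was seen. Like HINTW, HNRNPKL and UBAP2L2 (1.04) were dimly above background on both FAE arrays and on neither IFE array. Neither passed in limma (adjusted p = 0.128 and 0.327), and the remaining W-linked genes did not have this pattern. NEDD4L (216 and 349) and MBD2 (24.7 and 13.7) had clear signal on IFE replicates 1 and 2, where HINTW was under background. Whether their probe sets read only W-linked transcripts was not tested, so the median of the 6 genes cannot decide between the possibilities. Neither possibility could be settled, and the sex of the birds is not given.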
